A study of Mus musculus with 9 samples.

How the data were processed

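The series measured total RNA of mouse embryos at embryonic day 7.5 (E7.5), the stage of gastrulation, on 9 one-colour Affymetrix arrays. Per the labels, 3 kinds of embryo pool were compared: about 50 pooled embryos in which beta-catenin (gene Ctnnb1) was deleted where the cytokeratin 19 promoter expressed Cre recombinase (the conditional knockout), a pool carrying 1 floxed and 1 deleted allele of the gene (floxed/deleted), and a pool carrying 1 wild-type and 1 floxed allele (wild type/floxed). The last 2 served as controls. The labels do not say whether these 2 pools carried Cre or how many embryos they held. A floxed/deleted pool with Cre would have the knockout's genotype, so every comparison with it rests on the unstated absence of Cre. Each genotype was hybridised to 1 array of each of 3 designs, called A, B and C here (murine genome U74 version 2). The designs carry different probe sets, so their arrays are not replicates of one another. There was 1 pool per genotype and design, and no comparison has a replicate check. No significance test was run on an expression difference and no p-value was computed. Explanations were tested by setting a value against a bar. The number of arrays limits the precision of every value.

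The deposited values were intensity, on a linear scale with 1 value per probe set. The method that summarised the probes, the scaling target and the labelling protocol were not given in the sources used here. The deposited arrays had already been brought to a common level, because the mean without the lowest and highest 2% of values was 150.0 or 150.1 on each. Medians ran from 54.9 to 60.7 on design A, from 87.3 to 93.1 on design B and from 77.9 to 83.4 on design C. Present or absent calls were not used here.

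Within each design the arrays were scaled to equal trimmed means, which moved the values by almost nothing. Values below the pooled median of the design were then set to that median (57.3 on A, 90.0 on B, 80.9 on C) and log2 was taken. This floor is a rule of the analysis and not a detection limit. A probe set was measured if at least 1 of its 3 values lay above the floor, which left 24543 of 36899 probe sets, and 12860 lay above it on all 3 arrays. A probe set stood apart in a pool when it was at least 2-fold lower than both other pools, or at least 2-fold higher than both. Folds given here are against the nearer of the other pools, and "at least" marks a fold in which 1 side is at the floor. The same count was made for each control pool as a background. To give a background for a single probe set, its difference was set beside those of 1000 probe sets of similar brightness on the same design. The percent of their values in the 2 control pools that stood as far from both others in that direction is called the background percent.

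Gene names came from the platform annotation, with symbols checked through the gene table of assembly GRCm38.p6. Of all probe sets, 29197 had 1 symbol, 724 had several and 6978 had none in that annotation. Only those with 1 symbol were named. No symbol changed, and 87 probe sets had a gene that the table does not hold. Probe sets whose suffix marks sequence shared between transcripts or an incomplete probe choice numbered 8897.

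The scaling, floor, thresholds, 23 gene lists, 15 alternative settings and the rule for named genes were fixed before the data were examined. The lists covered Wnt targets, Wnt pathway components, genes recalled from the study, primitive streak and nascent mesoderm, definitive endoderm, visceral endoderm, cardiac, node and axial mesendoderm, epiblast and neuroectoderm, trophoblast and extraembryonic ectoderm, blood, endothelium and allantois, parietal endoderm and basement membrane, maternal decidua and immune cells, Hox and posterior genes, Nodal, BMP and FGF signalling, epithelial adhesion, proliferation, p53 and apoptosis, hypoxia and glycolysis, stress and immediate early genes, interferon response, sex-linked genes and ribosomal proteins. A list's shift was the median over its measured genes (1 probe set per gene, the brightest) of the log2 value in the knockout minus the mean log2 value of both controls. The same was done for floxed/deleted minus wild type/floxed. Each median has its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. Members at least 1.5-fold from both controls were counted. A list of paraxial mesoderm genes and a list of primitive erythroid genes were written after the other lists had been looked at, and so were 2 further settings.

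The rule named Ctnnb1 and Krt19 always. It took the 12 lower and 12 higher genes with the largest fold from the nearer control among probe sets above the floor on all 3 arrays, and up to 5 per direction with 1 side at the floor. Clone and locus names were left out. For floxed/deleted against wild type/floxed it took 8 per direction. From each list it took up to 4 members at least 1.5-fold from both controls, or otherwise the 2 brightest. Grsf1 and Ifitm1 were always named because they were recalled from the study of these samples.

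The steps were tested on simulated data built from the real mean signals and the differences between the control pools, with 200 probe sets changed on each design. On design A, 23.9% of simulated 2-fold, 61.2% of 3-fold and 80.3% of 4-fold changes in the knockout were recovered among 12488 probe sets. On design C the shares were 26.9%, 50.7% and 59.1% among 11934 probe sets. Each share is of 66 or 67 changed probe sets, all with a mean signal above the floor, so dimmer ones are not covered. Among unchanged probe sets the simulated knockout, floxed/deleted and wild type/floxed pools had 133, 137 and 126 apart on A, 393, 442 and 450 on B, and 1057, 1026 and 1079 on C. The real counts were lower for every pool (90, 92 and 46; 229, 259 and 239; 739, 922 and 942), so the simulated ones are no background for the real ones. The recovered shares come from the same simulated noise and may differ on the real arrays. Lists of 20 genes lowered by 0.5 on the log2 scale fell outside the central 95% of random lists in 97 of 100 draws among 12547 simulated genes, and unshifted lists did so in 6 of 100. The simulated genes varied independently, so these rates do not cover lists whose genes vary together. A shift of 0.5 is also larger than that of every real list except the pair recalled from the study. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.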

Results

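Embryos at E7.5 were profiled as pools of 3 genotypes on 3 array designs. The conditional knockout removes beta-catenin, the transcriptional effector of canonical Wnt signalling and a component of cell junctions, from cells in which the cytokeratin 19 promoter drives Cre. Each genotype had 1 array per design, and whether its 3 arrays shared 1 labelled sample is not stated. Differences are therefore given as values without a test or an error. Across probe sets, the Spearman correlation between the arrays of a design was 0.871 to 0.880 on A, 0.740 to 0.766 on B and 0.578 to 0.621 on C. The standard deviation over measured probe sets of the log2 difference between the 2 control pools was 0.44 on A, 0.59 on B and 0.88 on C, so a single value on design C carries less weight.

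The targeted gene, Ctnnb1, had a signal of 1376 in the conditional knockout, 1509 in the floxed/deleted pool and 1773 in the wild-type/floxed pool. The knockout was 1.10-fold lower than the nearer control. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, so the value checks the genotype labels little. Krt19, the gene whose promoter drives Cre, had a signal of 232 in the knockout against 97.6 in floxed/deleted and 119 in wild type/floxed, 1.94-fold higher than the nearer control. Its other probe set lay below the floor on all 3 arrays.

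The first comparison asked how the knockout pool differed from both controls. Some Wnt targets and posterior patterning genes were lower in it. Cdx1, a homeobox gene that sets posterior identity, had a signal of 9.1 against 208 in floxed/deleted and 237 in wild type/floxed, at least 3.63-fold lower. Its log2 difference from the nearer control was -1.86, and it was -0.63 with a floor at the 70th percentile and -3.19 with one at the 30th. Wnt3a, a ligand of the posterior streak, stood at 23.3 against 179 and 218, at least 3.12-fold lower, though the log2 difference was -0.41 with a floor at the 70th percentile. Dll1, a Notch ligand of presomitic mesoderm, stood at 155 against 499 and 475, 3.07-fold lower, and of its 3 other probe sets 1 stood at 87.0 with both controls below the floor and 2 were below the floor on all arrays. Tbx6, a T-box factor needed for paraxial mesoderm, stood at 100.3 against 268 and 307, 2.67-fold lower.

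Of 15 measured Wnt targets, 6 were at least 1.5-fold lower than both controls and 0 were higher. Besides those 4 they were Ccnd1, which encodes cyclin D1, with 135 against 444 and 316, and the secreted Wnt inhibitor Notum with 616 against 1068 and 1093. A second Ccnd1 probe set was 1.91-fold lower, and another gave 127 in the knockout between 42.8 and 154 in the controls. Axin2, a widely used readout of the pathway, was not among them, with 336 against 292 and 436, nor were Lef1 (768 against 1058 and 800), Sp5 (737 against 994 and 706) and Nkd1 (267 against 373 and 141). In all, 9 of the 15 were lower than both controls by any amount. The median log2 shift of the list was -0.31, at the 0.07th percentile of matched random lists, and it was -0.03 between the controls. Over the alternative settings the shift in the knockout ranged from -0.73 to -0.26. Visceral endoderm genes, described below, were higher in the same pool. The 5′ to 3′ signal ratio of beta-actin, a sign of RNA quality, was lower in that pool than in both controls on each design, with 0.570 against 0.655 and 0.696 on A, 0.608 against 0.685 and 0.730 on B, and 0.613 against 0.698 and 0.681 on C. That of Gapdh lay between the controls on each.

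Hox and posterior genes had the lowest median of the 23 lists apart from the pair recalled from the study, at -0.35 and the 0.4th percentile. Hoxb1 had a signal of 83.5 against 241 and 326, 2.88-fold lower (-0.84 on the log2 scale with the 70th percentile floor), and Hoxb2 had 163 against 734 and 500, 3.06-fold lower. With Cdx1 these were the 3 of 12 measured members that were at least 1.5-fold lower than both controls, and 0 were higher, while 5 were lower by any amount. The same count against both other pools gave 0 lower and 3 higher in floxed/deleted. In wild type/floxed it gave 0 lower and 1 higher. As many members thus stood apart in floxed/deleted as in the knockout, though in the other direction. Hoxb4 (231 against 381 and 235) was lower than the nearer control by less than 1.5-fold. Hoxb6 (89.0 against 71.6 and 109) and Hoxb8 (106 against 135 and 97.2) lay between the controls. Between the controls the list stood at -0.20, at the 5.39th percentile, but at 0.47 with a floor at the 30th percentile and 0.48 with no floor.

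**Figure D1:**
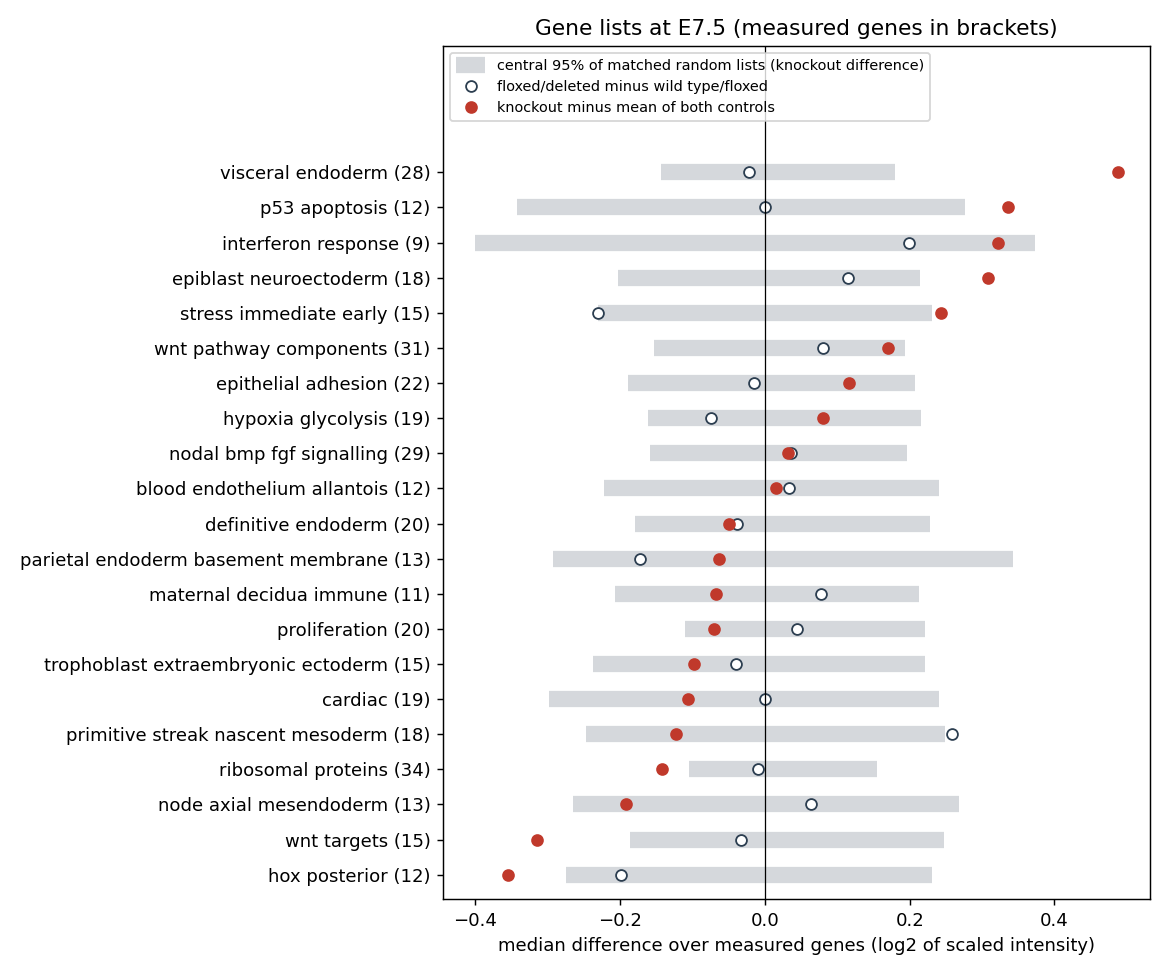
Median log2 difference (horizontal axis) of those of the 23 gene lists fixed at the start that had at least 5 measured genes, 1 list per line. Filled points give the knockout minus the mean of both controls, open points give floxed/deleted minus wild type/floxed, and bars give the central 95% of random lists matched on expression for the knockout difference. Visceral endoderm lies farthest right at 0.49, and Hox and posterior genes lie farthest left at -0.35.

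Visceral endoderm genes were higher in the knockout pool. The visceral endoderm is the absorptive epithelium around the embryo and makes apolipoproteins and nutrient receptors. Apoa1, an apolipoprotein, had a signal of 16067 against 7336 and 6813 on design B, 2.19-fold higher (0.72 on the log2 scale with quantile normalization against 1.13), and 12786 against 6813 and 6545 on design A, 1.88-fold higher. Apom was 2.07-fold higher (1724 against 713 and 832) and Apoa4 was 1.90-fold higher (851 against 354 and 447). The iron carrier Trf stood at 175 with both controls below the floor, at least 1.94-fold higher, but at a log2 difference of 0.06 with the 70th percentile floor. Of 28 measured members, 9 were at least 1.5-fold higher than both controls and 0 were lower, and 23 were higher than both by any amount. The median was 0.49, at the 100th percentile of random lists, against -0.02 between the controls. Ttr (528 against 451 and 465) and Hnf4a (422 against 380 and 469) were close to the controls.

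Epiblast and neuroectoderm genes went both ways. Slc7a3, an amino acid transporter, was 2.69-fold higher (976 against 363 and 255). Utf1, a chromatin factor of pluripotent cells, was 2.53-fold higher (2735 against 1080 and 795), and Sox2 was 2.17-fold higher (233 against 77.9 and 107). The de novo methyltransferase gene Dnmt3b was 1.64-fold higher and Pou3f1 was 1.80-fold higher. Gbx2, a homeobox gene of the hindbrain border, was at least 2.67-fold lower (7.3 against 153 and 239; -0.19 on the log2 scale with the 70th percentile floor), and Irx3 (2.16-fold) and Crabp2 (1.73-fold) were lower as well. Of 18 measured members, 5 were higher and 3 lower. The median of 0.31, at the 99.5th percentile, was -0.19 on design A alone and 0.0026 with floxed/deleted as the sole control. On design C a second Utf1 probe set was not higher, at 97.7 against 126 and 109, and another gave 42.6 against 72.5 and 102. Of 3 further Slc7a3 probe sets there, 1 was lower, at 241 against 338 and 370, 1 was at least 2.48-fold higher and 1 was below the floor on all arrays.

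**Figure D2:**
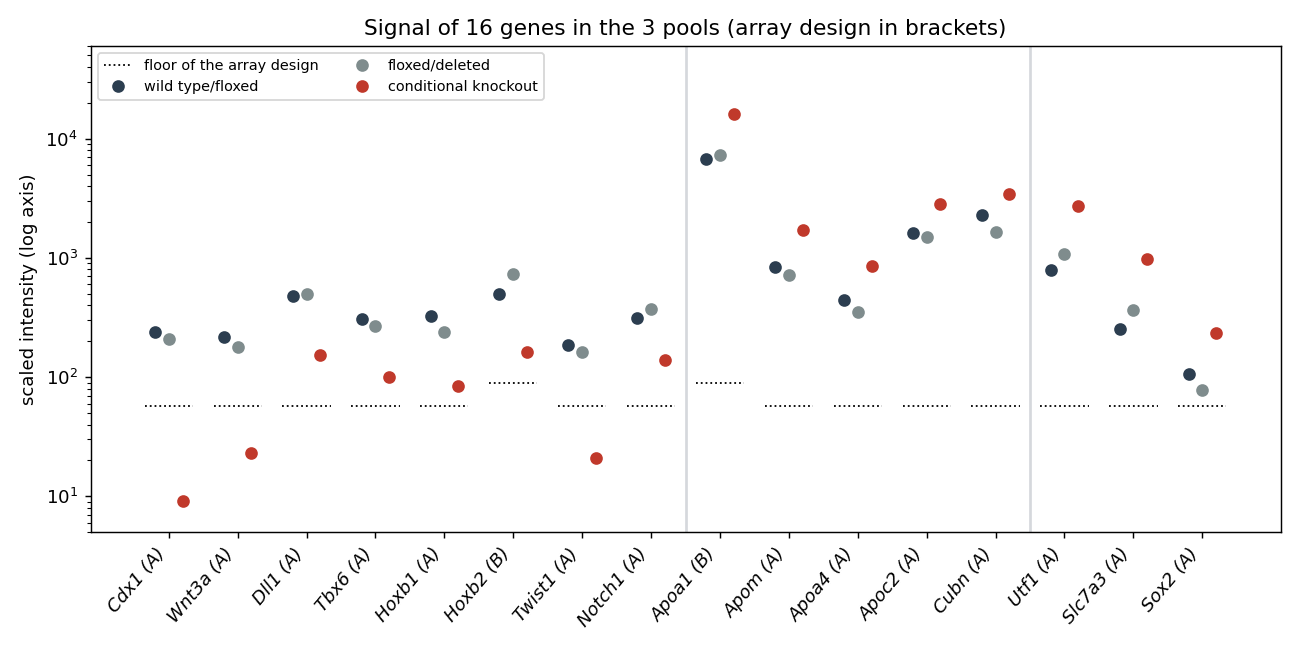
Scaled intensity on a log axis of 16 genes in the 3 pools, with the array design in brackets and a dotted line at the floor of that design. Each point is 1 array. The knockout is the lowest of the 3 for the 8 genes on the left, from Cdx1 to Notch1, and the highest for the visceral endoderm and epiblast genes to their right. The genes are a selection that shows these differences. Left out are Gbx2, Irx3 and Crabp2 of the epiblast list, which were lower, and the visceral endoderm genes Ttr and Hnf4a, which were close to the controls.

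Primitive streak and nascent mesoderm genes had a median of -0.12, at the 22.2nd percentile. Wnt3a, Tbx6 and the secreted Wnt antagonist gene Frzb were the 3 of 18 members at least 1.5-fold lower, Frzb by at least 2.21-fold, or -0.12 on the log2 scale with the 70th percentile floor, and by 1.31-fold on its other probe set. The mesoderm factors Mesp1 (344 against 427 and 310) and Eomes (131 against 98.7 and 67.5) were not lower than both controls. By the same count 3 streak members were lower and 1 higher in wild type/floxed, and 0 lower and 1 higher in floxed/deleted. Cardiac genes were mixed, with 5 of 19 lower and 3 higher at a median of -0.11 and the 26.6th percentile. Smarcd3, a chromatin remodelling subunit used in heart development, was 3.12-fold lower than wild type/floxed and 4.84-fold lower than floxed/deleted. Tbx20 was at least 3.65-fold lower, or -0.84 on the log2 scale with the 70th percentile floor, and its other probe set gave 84.8 against 95.9 and 50.0. The troponin gene Tnni1 was at least 2.40-fold lower, or -0.04 on the log2 scale with the 70th percentile floor. Myh7, a myosin heavy chain gene, was at least 1.90-fold higher but not measured with that floor, and its other probe set gave 20.3 against 18.9 and 70.5. Other probe sets of Smarcd3 gave 175 against 111 and 233, and 183 against 217 and 403.

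Definitive endoderm genes had a median of -0.05, at the 30.02nd percentile. Among 20 measured members, Pyy (at least 1.78-fold, and 0 on the log2 scale with the 70th percentile floor) and Shh (at least 1.58-fold, and not measured with that floor) were lower and Krt19 was higher. By the same 1.5-fold count, 3 members were lower and 1 higher in floxed/deleted, and 2 lower and 0 higher in wild type/floxed. Sox17, a factor of early endoderm, stood at 225 against 346 and 291. Node and axial mesendoderm genes stood at -0.19 and the 11.7th percentile, and the ciliary factor Foxj1 was at least 2.44-fold lower (57.2 against 146 and 140), or -0.06 on the log2 scale with the 70th percentile floor. Of 13 measured node members, 2 were at least 1.5-fold lower than both other pools in each of the 3 pools. Wnt pathway components had a median of 0.17, at the 95.5th percentile, with 3 of 31 members higher and 0 lower. These were the receptor gene Fzd5 (1.72-fold), Tcf7l1 (1.87-fold) and Tcf7l2 (1.79-fold), the last 2 encoding Tcf transcription factors. With the 70th percentile floor Tcf7l2 stood at 0.14 on the log2 scale. A second probe set of Tcf7l1 was 1.36-fold higher and a second one of Tcf7l2 was 1.74-fold higher. The same count for this list gave 4 lower and 2 higher in floxed/deleted. In wild type/floxed it gave 2 lower and 0 higher, so the knockout did not have the most members apart.

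Lists of other tissues stayed inside the central 95% of random lists. Trophoblast and extraembryonic ectoderm genes stood at -0.10 (37.2nd percentile), and at 0.17 without shared-suffix probe sets. Wnt7b was 1.99-fold lower and Esrrb 2.18-fold higher, though Esrrb had a background percent of 19.3 and a log2 difference of 0.21 with the 70th percentile floor. Blood, endothelium and allantois genes stood at 0.016 (71.8th percentile), with Etv2, a factor of endothelial precursors, 1.51-fold higher, and under 1.5-fold with no floor (0.53). Parietal endoderm and basement membrane genes stood at -0.06 (31.8th percentile), with Fst 1.84-fold lower, Pga5 1.81-fold higher and Sparc 1.57-fold higher. Pga5 stood at 0.27 with the 70th percentile floor and Sparc at 0.58 with no floor, both under 1.5-fold. Maternal decidua and immune genes stood at -0.07 (38.2nd percentile), with C1qb at least 2.01-fold higher, though not measured with the 70th percentile floor, and Laptm5 1.65-fold higher. Of 2 other Laptm5 probe sets, 1 was at least 1.93-fold higher and 1 gave 26.9 against 28.8 and 58.9.

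Among signalling and cell state lists, p53 and apoptosis genes stood at 0.34 (98.7th percentile), with 1 of 12 members, Sesn2, at least 2.32-fold higher, with a background percent of 10 and a log2 difference of 0.18 with the 70th percentile floor. Stress and immediate early genes stood at 0.24 (98.1st percentile), and at -0.23 (1.87th percentile) between the controls. Zfp36 was at least 2.30-fold higher, though not measured with the 70th percentile floor, and Ier3 at least 2.75-fold lower, but a second Ier3 probe set gave 35.4 against 73.8 and 24.5, and the first stood at -0.43 on the log2 scale with that floor. Ribosomal protein genes stood at -0.14 (0.3rd percentile), and at -0.05 with equal medians and -0.03 with quantile normalization. Rpl13 was 3.73-fold lower and Rps14 was 1.52-fold lower, both on design C, and Rps14 was under 1.5-fold with equal medians (-0.51) and no floor (-0.54). Interferon response genes stood at 0.32 (95.8th percentile), with 0 of 9 at least 1.5-fold from both controls. Bst2 stood at 767 against 415 and 564, and Irf7 at 389 against 325 and 289.

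Nodal, BMP and FGF signalling genes stood at 0.03 (60.4th percentile), with Msx2 1.65-fold lower and Smad7 1.60-fold higher. With the 70th percentile floor they stood at -0.26 and 0.19, and Smad7 at 0.57 with no floor, all under 1.5-fold. Epithelial adhesion genes stood at 0.12 (86.5th percentile), and Krt19 was the single member 1.5-fold from both controls. Proliferation genes stood at -0.07 (7.3rd percentile), with Ccnb2, which encodes cyclin B2, 1.72-fold lower (1108 against 2041 and 1905). Hypoxia and glycolysis genes stood at 0.08 (78.2nd percentile), with Ndrg1 at least 1.56-fold lower and Egln3 1.53-fold lower. Their other probe sets gave 32.3 against 80.3 and 38.8 for Ndrg1, and 201 against 198 and 62.7 for Egln3. With equal medians both were under 1.5-fold (-0.56 and -0.53), with no floor Egln3 was (-0.57), and with the 70th percentile floor Ndrg1 was not measured. Of the sex-linked genes, Kdm5d stood at 159 against 105 and 117, and Xist at 19.9 against 42.2 and 80.5. In all, 8 of the 23 lists lay outside the central 95% of random lists in the knockout, and 1 did so between the controls. For lists of independently varying genes 1.15 would do so. That number is no background for these lists, because genes of the same tissue can vary together and some lists share genes. The pair recalled from the study is also among the 8.

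Grsf1 and Ifitm1, recalled from the study of these samples and so not independent evidence, were lower in the knockout. Grsf1, an RNA-binding protein gene, stood at 246 against 376 and 508, 1.53-fold lower, and at 284 against 330 and 408 on a second probe set, 1.16-fold lower. The first was under 1.5-fold with equal medians (-0.47) and no floor (-0.57). Ifitm1, an interferon-induced membrane protein gene, stood at 23.2 against 80.1 and 79.8, at least 1.39-fold lower. The median of this pair was -0.65, at the 1.47th percentile, and ranged from -1.31 to -0.54 over the alternative settings.

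Ranked by fold alone, the lower genes above the floor on all arrays were led by Stat2, a factor of interferon signalling, at 94.9 against 1097 and 1149 (11.6-fold). They went on with Pafah1b2 (8.16-fold), Grwd1 (5.03-fold), Itgb1bp1 (4.11-fold), Iah1 (4.10-fold), Haus3 (4.02-fold), Rpl13, Traf2 (3.71-fold), Coq8b (3.66-fold), Ctif (3.65-fold), the mTOR inhibitor gene Ddit4 (3.61-fold) and the imprinted gene Grb10 (3.50-fold). The higher genes were Rasgef1b (5.27-fold), the splicing factor gene Snrpc (4.64-fold), the fructose transporter gene Slc2a5 (4.47-fold), Btbd9 (4.10-fold), Pin4 (4.02-fold), Cep89 (3.51-fold), Prss58 (3.21-fold), Ttc16 (3.20-fold), Rita1 (3.20-fold), Gchfr (3.16-fold), Acot6 (3.10-fold) and Elk4 (3.01-fold). Below the floor in the knockout were Fam120b (at least 7.54-fold lower), Ift122 (at least 5.46-fold), Cinp (at least 5.32-fold), Atcay (at least 4.81-fold) and Lce1i (at least 4.38-fold). Below the floor in both controls were Tkfc (at least 4.67-fold higher), Pigk (at least 4.66-fold), Mfap5 (at least 4.62-fold), Iqce (at least 4.46-fold) and Arhgap25 (at least 4.22-fold).

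Most of these top ranks were on design C, 9 of the 12 lower and 10 of the 12 higher genes, and 8 and 6 of them had a suffix for shared or incomplete probe sets. Other probe sets of the same genes seldom agreed. The 12 lower genes had 14 other measured probe sets, of which 1, of Coq8b, was also at least 1.5-fold lower and 0 were as much higher. The 12 higher genes had 9, of which 3 were at least 1.5-fold higher, for Snrpc, Slc2a5 and Gchfr, and 2 were as much lower, for Rasgef1b (69.5 against 234 and 474) and Cep89 (37.4 against 154 and 103). Further probe sets gave 803 against 776 and 934 for Snrpc, 46.6 against 81.0 and 115 for Slc2a5, and 118 against 137 and 85.7 for Stat2. The 5 genes below the floor in the knockout had 3 other measured probe sets, and the 5 below it in both controls had 4. Of these, 0 were at least 1.5-fold from both controls in either direction. For Fam120b they gave 260 against 246 and 282, and 349 against 229 and 524. The members named from the lists, 49 in all, had 20 others, with 4 in the same direction by 1.5-fold and 0 in the other. Background percents were 0 for Stat2, 0.1 for Pafah1b2 and 0.8 for Grwd1, and for Coq8b the background percent was 3.75. These genes were chosen for the fold that the background percent ranks, so low values follow from the choice and lend them no support. Among genes named by the rule and at least 1.5-fold from both controls, the highest were 19.3 for Esrrb, 13.1 for Rps14, 10.85 for Tcf7l2, 10.75 for Egln3, 10 for Sesn2, 8.15 for Pga5, 7.6 for Laptm5, 6.05 for Shh and Pyy, 5.9 for Frzb, 5.85 for Trf and 5.45 for Ier3. Ctnnb1, 1.10-fold lower, had 13.35. For Ccnd1 the background percent was 7.25.

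Over all designs, 448 probe sets were at least 2-fold lower and 610 at least 2-fold higher in the knockout than in both controls, 1058 of 24543 measured. Among probe sets above the floor on all arrays the balance was the other way, with 197 lower and 137 higher, as it was among the brightest 25%, with 113 and 50. The same count was 1273 for floxed/deleted and 1227 for wild type/floxed, so over all designs the knockout pool had no more probe sets apart than either control pool. On design A the counts were 90 for the knockout, 92 for floxed/deleted and 46 for wild type/floxed, and 53 of the 90 were lower. Without design C the knockout had 163 lower and 156 higher, more in sum than the 285 of wild type/floxed and fewer than the 351 of floxed/deleted. Among all genes, 5.68% were at least 1.5-fold lower and 6.45% at least 1.5-fold higher in the knockout. The shares were much the same in the controls, with 5.52% and 7.48% in floxed/deleted and 5.56% and 6.65% in wild type/floxed. These counts moved with the floor, the threshold and the design, and the values are given with the alternative settings.

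**Figure D3:**
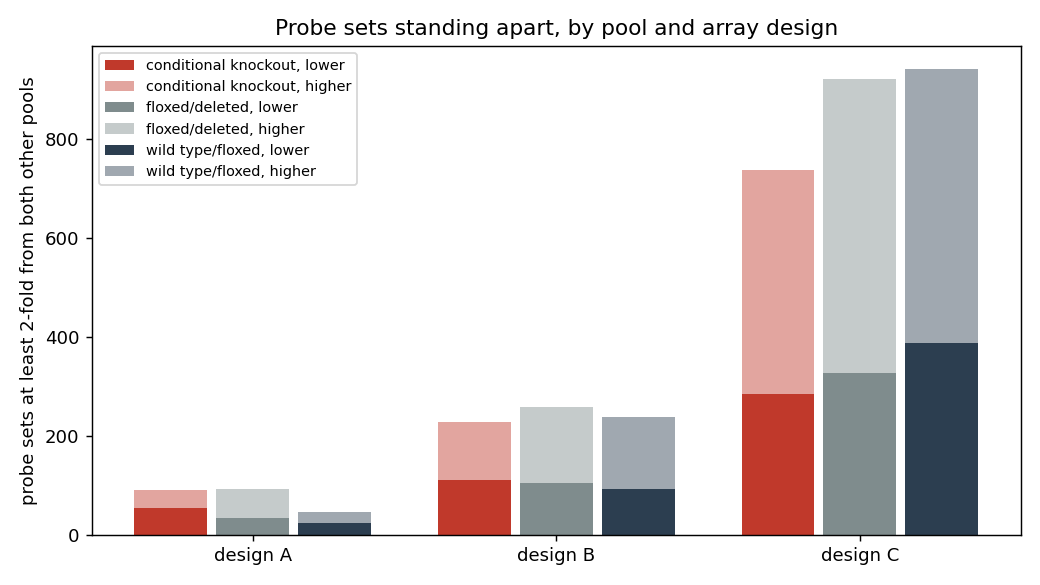
Number of probe sets at least 2-fold from both other pools (vertical axis) for each pool on each array design, with the lower ones at the base of each bar and the higher ones above. On design C all 3 pools have between 739 and 942, and the knockout has the fewest there.

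The second comparison set the floxed/deleted pool, with 1 intact allele, against the wild-type/floxed pool. Of the 8 lists outside the central 95% of random lists in the knockout, visceral endoderm (-0.02), Wnt targets (-0.03), p53 and apoptosis (0.00) and ribosomal proteins (-0.01) were near 0 here. The other 4 were epiblast and neuroectoderm at 0.12, Hox and posterior genes at -0.20, the pair recalled from the study at -0.21 and stress and immediate early genes at -0.23. Cdx1 (208 and 237), Dll1 (499 and 475) and Tbx6 (268 and 307) were close between these pools. Primitive streak and nascent mesoderm genes stood at 0.26, at the 95.5th percentile. The stress and immediate early list was the 1 list outside the central 95% of random lists.

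By fold, floxed/deleted was lower for Nrsn2 (107 against 903, 8.45-fold), Ppp1r37 (7.29-fold), Zfp787 (6.76-fold), Fnbp1 (6.72-fold), the synaptic adhesion gene Clstn3 (6.45-fold), Spdye4b (6.21-fold), Plpp4 (6.19-fold) and Slc66a1 (5.57-fold). It was higher for Cmtm3 (1419 against 161, 8.84-fold), the Gata cofactor gene Zfpm2 (8.30-fold), the heparan sulfate synthesis gene Ext1 (7.27-fold), Slc25a33 (6.76-fold), Ncan (6.67-fold), Vasn (6.45-fold), Tmem131l (5.92-fold) and Gorasp2 (5.77-fold). All 8 lower genes and 6 of the 8 higher ones were on design C. In all, 1565 probe sets were at least 2-fold lower and 1700 at least 2-fold higher in floxed/deleted. With equal medians the balance turned, to 1653 lower and 1537 higher. The knockout against floxed/deleted gave 1636 lower and 1438 higher, and against wild type/floxed 1538 lower and 1470 higher.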

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

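The spike-control comparisons in this part were chosen only after the values had been seen. Bacterial control transcripts such as Dap and Thr have probe sets on every array and are not expressed by mouse tissue, and their signal differed between the pools. The 198 control probe sets of the arrays, these included, were left out of the genes ranked by fold. They stayed in the counts of probe sets apart, so those counts are not of mouse genes alone. The Dap 3′ probe set was above both other pools in the knockout on each design, by at least 6.04-fold on A, 3.09-fold on B and at least 12.7-fold on C. The Thr 3′ probe set was above both others in wild type/floxed, by 8.36-fold on A, 6.21-fold on B and 7.05-fold on C. It was also higher in the knockout than in floxed/deleted, by at least 3.12-fold on A, at least 7.30-fold on B and at least 9.72-fold on C. No explanation was tested for these values.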

How the results depend on the processing

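The restriction to the brightest 25% of probe sets and the setting without design C were chosen after seeing the data. Counts below are in the order knockout lower, knockout higher, floxed/deleted apart, wild type/floxed apart, then floxed/deleted lower and higher than wild type/floxed. They were 1563, 1666, 3916, 3662, 4145 and 4540 with a floor at the 30th percentile, and 90, 150, 258, 279, 380 and 417 at the 70th. With log2 of the value plus the 30th percentile they were 1247, 1155, 2864, 2673, 3467 and 3758. A 1.5-fold threshold gave 1381, 1803, 3570, 3404, 3739 and 3906, and 3-fold gave 94, 125, 279, 255, 401 and 451. With 1 probe set per gene they were 240, 249, 529, 523, 665 and 765. Design A alone gave 53, 37, 92, 46, 101 and 147, the brightest 25% gave 113, 50, 164, 201, 216 and 266, and leaving out design C gave 163, 156, 351, 285, 486 and 520. With 1 control the knockout counts were 1636 and 1438 (floxed/deleted) or 1538 and 1470 (wild type/floxed). The threshold, the number of probe sets and the number of controls act on these counts by construction, and for the floor the cause was not tested. Wnt targets stayed below 0 under all settings run, with -0.70 on design A alone, -0.60 without design C and -0.73 with the higher floor, and Hox and posterior genes ranged from -0.52 to -0.26. Visceral endoderm ranged from 0.39 to 0.63. Epiblast and neuroectoderm reversed to -0.19 on design A alone and was 0.0026 with floxed/deleted as control, and the pair recalled from the study was -1.31 with the lower floor (the cause was not tested). Trophoblast moved to 0.17 without shared-suffix probe sets, and Hox between the controls to 0.47 with the lower floor and 0.48 with no floor. Equal medians moved the 5126 probe sets of design A above the floor on all arrays by a median of 0.09 (knockout) and -0.10 (between the controls). Of 500 values of list shifts under the alternatives, 491 moved by less than the half-width of the random range. Of 704 values of named genes, 654 moved by less than the spread between the controls, and none reversed, but of 82 named genes at least 1.5-fold from both controls 22 fell under 1.5-fold in some setting. With the 70th percentile floor these were 16 of the 77 still measured, namely Wnt3a (-0.41), Ier3 (-0.43), Pga5 (0.27), Twist1 and Msx2 (-0.26), Esrrb (0.21), Smad7 and Gbx2 (0.19 and -0.19), Sesn2 (0.18), Tcf7l2 (0.14), Frzb (-0.12), Foxj1 (-0.06), Trf (0.06), Tnni1 (-0.04), Pyy and Tcf15 (0), and C1qb, Myh7, Ndrg1, Shh and Zfp36 were no longer measured. Shh also moved by over 1.5 times with the 30th percentile floor and Cep89 with the 70th, and both kept their direction where measured. Others that moved by over 1.5 times with the 70th percentile floor and kept 1.5-fold were Cdx1 (-0.63), Ddit4 (-0.65), Wnt7b (-0.66), Hoxb1 and Tbx20 (-0.84), Haus3 and Coq8b (-1.16), Itgb1bp1 (-1.28), Slc2a5 (1.32), and the genes with 1 side at the floor, from -1.89 to -1.10 (Fam120b to Lce1i) and 1.05 to 1.32 (Arhgap25 to Pigk). The 30th percentile floor moved Cdx1 to -3.19, Wnt3a to -2.94, Twist1 to -2.83, Gbx2 to -2.75, Ier3 to -2.64, Frzb to -2.29, Tcf15 to -2.14, Pyy to -1.66, Ndrg1 to -1.49, Trf to 1.51 and Myh7 to 1.59. The genes that fell under 1.5-fold with equal medians were Grsf1 (-0.47), Rps14 (-0.51), Egln3 (-0.53) and Ndrg1 (-0.56), and with no floor Grsf1 (-0.57), Egln3 (-0.57), Rps14 (-0.54), Etv2 (0.53), Sparc (0.58) and Smad7 (0.57). With equal medians the knockout had 380 lower and 738 higher. Single values on design C are limited by the spread between the controls there, 0.88 against 0.44 on design A.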

Other observations

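In this part, the genes of the next paragraph were chosen after their values were seen. The tests of RNA degradation, younger embryos and a smaller embryo proper were chosen only after the result was seen. For RNA degradation and the smaller embryo proper, the bar for excluding the explanation was also raised after the values of the test were known. The paraxial mesoderm list and the test on bright probe sets were written before the values they measure were seen, though after the first lists had been looked at.

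On design A, where the arrays of a design differed least, 53 probe sets were at least 2-fold lower and 37 at least 2-fold higher than both controls in the knockout. The genes described here were singled out from all designs and stand for no tested theme. Foxc2, a forkhead factor of paraxial mesoderm, stood at 68.2 against 233 and 323, 3.42-fold lower, while its other probe set was near the floor. Prrx2, a homeobox gene of mesenchyme, was at least 2.30-fold lower, but its probe set on design C stood at 196 against 202 and 86.7. Crabp1, a retinoic acid binding protein gene, was 2.15-fold lower, and the imprinted gene Phlda2 was 2.03-fold lower (1424 against 2895 and 3267). Nkx1-2, a homeobox gene of the posterior embryo, was lower on both designs that measured it, by 3.19-fold on C (130 against 558 and 414) and by at least 1.75-fold on A. Rbm24, an RNA-binding protein gene of early muscle and heart, stood at 121 against 441 and 364 on design B. Higher were the zinc-binding metallothionein gene Mt1 (865 against 319 and 339) and the zinc transporter gene Slc30a5 (316 against 81.0 and 116), but a design B probe set of Mt1 gave 755 against 517 and 744.

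A second list of paraxial mesoderm genes, none of them in the first lists, was lower in the knockout as well. Of 14 measured members, 5 were at least 1.5-fold lower than both controls and 0 were higher, with a median of -0.45. Twist1 was at least 2.81-fold lower (21.1 against 161 and 187), Notch1 was 2.27-fold lower (139 against 375 and 316) and 1.29-fold on its other probe set, Cited2 was 1.99-fold lower and the somite factor gene Tcf15 at least 1.74-fold lower. Lfng (137 against 132 and 131) and Hes1 (204 against 212 and 171) were not. With the 70th percentile floor the log2 differences of Twist1 and Tcf15 were -0.26 and 0. Between the controls the list stood at 0.011.

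The lower Wnt target, Hox and mesoderm genes were weighed against 2 technical or staging explanations and a biological one. Degraded RNA is not excluded, because the beta-actin 5′ to 3′ signal ratio was below both controls on 3 designs, down to 0.820 of a control's, while that of Gapdh was so on 0 designs. Loss of paraxial and presomitic mesoderm in the knockout may account for them, and the second list, at the 0.43rd percentile, had the low median this needs. That list covers the tissue of genes already seen to be lower. Younger embryos could lower it as well, so its median does not tell these explanations apart. Somewhat younger embryos in the knockout pool remain as a candidate explanation that cannot be told apart from the genotype, since 7 primitive erythroid genes, which come on at about this stage and mostly also stand in the blood list, had a median of -0.20 at the 8.78th percentile. That lies 0.15 above the Hox median of -0.35, less than the 0.29 that is the half-width of its random range.

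The higher visceral endoderm genes were weighed against a smaller embryo proper, with which every extraembryonic tissue would stand higher alike. The visceral endoderm median exceeded the trophoblast median by 0.59, against 0.39 for the half-widths of both random ranges together, and exceeded it by more than that in 11 of 12 alternative settings, but by 0.25 without shared-suffix probe sets. Trophoblast (-0.10) and parietal endoderm (-0.06, 31.8th percentile) did not stand higher, which this explanation needs if those tissues were in the pools. Without shared-suffix probe sets, though, trophoblast stood at 0.17. Some trophoblast members lay near the floor, such as Cdx2 (56.6 against 57.2 and 66.2) and Rhox6 (65.5 against 34.0 and 58.9), which weakens the comparison. Since 1 setting also missed the bar, a smaller embryo proper may hold and stays open. A larger share of visceral endoderm in the pool, from dissection or from the genotype, and a change of expression within that tissue were not tested and stay open. The brightest members include Amn at 12922 against 6390 and 8806, and Apoe, which other tissues also express, at 11812 against 9142 and 10236.

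Over all designs the knockout pool had no more probe sets apart than the control pools, though on design A it had 90 against 46 for wild type/floxed and without design C it had 163 lower and 156 higher against 285, and noise of dim probe sets was tested as the cause. Among the brightest 25% of each design the knockout had 163, floxed/deleted 164 and wild type/floxed 201, a ratio of 0.893 to the mean of the controls. Bright probe sets thus showed no excess in sum. On design C the standard deviation between the controls was 0.86 among the brightest 25%, against 0.88 over all measured probe sets. The count therefore cannot tell whether noise hides an excess. Among the brightest 25% on design A it was 0.33 for the knockout against floxed/deleted, 0.32 against wild type/floxed and 0.28 between the controls. Differences of stage or litter between the pools stay open as untested explanations. For 251 of the probe sets at least 2-fold apart in the knockout, the same genes had 143 other probe sets above the floor. Of these, 78 (54.5%, exact 95% interval 46.0 to 62.9) went in the same direction. The interval takes the probe sets as independent, though some are of the same gene, and measures no spread between pools. For floxed/deleted 95 of 175 and for wild type/floxed 101 of 193 went in the same direction.

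Cre recombinase from phage P1 is also a hybridisation control on these arrays, so its probe sets cannot show the transgene by themselves. The 3′ Cre signal was 4988 in the knockout against 2842 and 3341 on design C, 2513 against 2111 and 2569 on design B, and 994 against 1019 and 1087 on design A. The probe set for the B2 repeat was lower in the knockout on each design, with 13988 against 20602 and 17990 on A, 30473 against 61102 and 38132 on B, and 79509 against 91922 and 95232 on C. That for the B1 repeat was not, with 4957 against 4725 and 4987 on A, 10503 against 9499 and 9272 on B, and 21888 against 12284 and 12859 on C.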
